A study of Mus musculus with 15 samples.

How the data were processed

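Liver RNA of mice was sequenced in 15 libraries, 3 in each of 5 groups. Per the labels, control mice ate standard feed. The model diet mixed such feed (78.8%) with added cholesterol (1%), cholate as its sodium salt (0.2%), powdered egg yolk (10%) and lard (10%). The 3 other groups ate a high-fat diet whose composition the labels do not state, taken here to be that of the model, and received a flavonoid by oral gavage, which was quercetin at 200 mg/kg/day, myricetin at 75 mg/kg/day or kaempferol at 100 mg/kg/day. Feeding lasted 6 weeks. The labels do not state sex, strain, time of day at collection, fasting, or whether control and model mice were gavaged. They also do not say that the libraries of a group came from separate mice, so p-values of the gene tests measure the spread between libraries. Libraries are named by group and by the number in their title.

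Per the submitters' processing notes, the tools were HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 with the build GRCm38.p6, with no role or order given. The deposited table holds an expected count per gene and library, per the file headers a read count that is not scaled between libraries. These estimated counts were not whole in 5.37% of the values. The table covers 16809 genes, with no gene at 0 in every library. It also holds the authors' log2 fold change and the authors' DESeq2 q value for 4 comparisons, per the file headers. These served only for a count of genes with a q value under 0.05. The 30 columns of FPKM and TPM and the 15 columns of group averages were not used. Gene symbols and positions are those of the deposited table, and 16760 gene identifiers were found in the reference table. Strand was not stated, so reads of overlapping genes on opposite strands may be mixed. Reads shared between near-identical genes were divided by the authors' counting, so values of the Nat8f, Mup, Cyp4a, Cyp2c, Gstm, Serpina1, Mt and ribosomal protein genes are uncertain in part.

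Expected counts were rounded and genes with low counts were removed with filterByExpr, which left 12658 genes. Counts were scaled with TMM factors and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, over all 15 libraries with 1 mean per group and 10 residual degrees of freedom. Each comparison was tested 2-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene passed at an adjusted p under 0.05. An F test covered the 4 high-fat groups. CPM were computed on the TMM-scaled library size. The common biological coefficient of variation was 0.155. A standard error was taken as the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. The 95% intervals follow from it, so both are approximate. The median standard error of a log2 fold change was 0.162 for the model against the control, with a median 95% interval of 0.344 to either side.

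Gene lists for liver pathways, stress responses, cell type markers, time of day, sex bias, and RNA quality and handling were tested when at least 5 members passed the filter. This left 35 lists. The ribosomal protein, immediate early and heat shock lists were included for RNA quality and handling. A mitochondrial genome list meant for the same had 0 genes in the deposited table. Some genes stand in more than 1 list, such as Cidec in those of lipid droplets and adipocytes. The list test was camera of limma 3.58.1 with its preset correlation, which asks whether members moved more than other genes, with Benjamini-Hochberg adjustment over the lists. Its p-values rest on that preset correlation, not on how members varied together between libraries. In the model against the control, estimated correlations were 0.454 for cholesterol synthesis and 0.705 for ribosomal proteins. Camera p-values with the preset correlation may thus be far too small. Camera with a correlation estimated for each list and fry were the alternatives. For each list, genes were also counted with p-values adjusted over the list alone. Gene lists, tests, the rule for named genes and the alternatives were fixed before the data were examined, except for the clock score as an alternative and some tests of explanations, which were added afterwards.

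The text names genes by this rule. Some genes that it takes are not reported here. Part 1 is 12 fixed genes of lipid metabolism and aryl hydrocarbon response (10 of them Cyp7a1, Cyp8b1, Sqle, Fasn, Scd1, Srebf1, Cpt1a, Abcg5, Cd36 and Cyp1a1). Part 2 is the 6 highest and 6 lowest log2 fold changes among genes that passed, whose CPM ranges did not overlap between groups and whose higher mean was at least 5 CPM, leaving out symbols made of Gm or LOC plus digits or ending in Rik. Part 3 is up to 3 passing members per direction, by smallest p, of each list that passed or had at least 3 passing members. Part 4 is, where no gene passed, the 3 smallest unadjusted p-values per direction. Part 5 lets a gene named in one comparison be given in the others. Every named gene that passed had CPM ranges that did not overlap between the groups, which chance alone gives for 10% of genes with 3 against 3.

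The method was tested on simulated counts with 200 changed genes in each of 7 comparisons, on 12536 to 12559 genes. The 25 cholesterol synthesis and uptake genes were also lowered 1.5-fold, and they enter the calls but not the recovery. The method recovered 28.4% to 37.3% of genes changed 1.5-fold, 70.1% to 84.8% of those changed 2-fold and 92.3% to 100% of those changed 4-fold. False calls were 0.69% to 7.84% of the calls. Genes were drawn independently with the fitted spread, so these rates may be better than in the data. The 3 flavonoid groups share the model libraries, so covariances and correlations between comparisons were set beside 100 simulations of groups that equal the model. These simulations gave 1468.2 genes on average between model and control, against 565 in the data, so they do not match the data in this count. Genes were drawn independently, so the spread of those simulations is a lower limit.

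The alternatives were RLE factors, no filter on low counts, a mean of at least 1 CPM, a change of at least 2-fold, an adjusted p under 0.1, only the 2 groups compared, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, and the clock score as a covariate. The clock score is the first principal component of the log2 CPM of the circadian clock list.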

Results

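The series measured liver transcripts by RNA sequencing in 5 groups of 3 libraries, a standard-feed control, a high-fat, high-cholesterol model, and 3 groups given quercetin, myricetin or kaempferol on a high-fat diet, taken here to be that of the model. Mean library totals, in M expected counts, were 16.4 ± 0.35 in the control, 16.96 ± 0.607 in the model, 16.5 ± 0.314 with quercetin, 16.8 ± 0.866 with myricetin and 17.1 ± 0.266 with kaempferol (SD, n = 3). Each library had counts for 14601 to 14919 genes, and albumin took 4.28% to 7.87% of the counts. Below, levels are CPM as mean ± SD with n = 3 libraries per group, changes are log2 fold changes ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

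The model against the control asks how the cholesterol-rich diet altered liver transcripts. Genes of cholesterol synthesis and uptake were lower in the model. Of 25 members tested, 9 fell and the other 16 did not pass (16 fell when adjusted over the list alone), with a median log2 fold change of -0.81. Tm7sf2, a sterol reductase, fell from 133.9 ± 14.7 to 59.1 ± 12.5 CPM, a change of -1.18 ± 0.16 (edgeR adjusted p = 0.00413). Sqle, squalene epoxidase, changed by -3.67 ± 0.70 (edgeR adjusted p = 0.0195). Fdft1, squalene synthase, fell by 0.90. Sqle and Fdft1 missed the threshold without some libraries, with edgeR adjusted p-values as high as 0.0759 for Sqle without model replicate 1 and 0.0839 for Fdft1 without model replicate 5. The camera adjusted p of the list was 4.64e-15, and adjusted p = 0.272 with an estimated correlation.

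Srebf1, a transcription factor of lipid synthesis (GRCm38.p6 chromosome 11, 60199084 to 60224186), rose from 164.8 ± 42.2 to 379.7 ± 37.5 CPM, a change of 1.20 ± 0.17 (edgeR adjusted p = 0.00413). The sterol efflux list of LXR targets had 1 member that rose and 1 that fell among 14 (5 higher and 1 lower adjusted over the list alone). Its median was 0.37, with a camera adjusted p of 0.000961, and adjusted p = 0.195 with an estimated correlation. Abca1, the cholesterol efflux transporter, rose by 0.70 ± 0.11, and Npc2, a lysosomal cholesterol carrier, fell by 0.43. Among 20 fatty acid synthesis genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.229). Fasn, fatty acid synthase, differed by -0.48 ± 0.37 (edgeR adjusted p = 0.497) and Scd1, a fatty acid desaturase, by 0.30 ± 0.35 (0.664). The bile acid synthesis enzymes Cyp7a1 and Cyp8b1 differed by 1.21 ± 0.63 (0.293) and 0.03 ± 0.22 (0.957), the sterol transporter Abcg5 by 0.98 ± 0.34 (0.118), the fatty acid uptake gene Cd36 by 1.14 ± 0.46 (0.18), the fatty acid oxidation gene Cpt1a by -0.04 ± 0.12 (0.885) and the aryl hydrocarbon receptor target Cyp1a1 by -0.19 ± 0.31 (0.768), none of which passed the edgeR test.

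Genes of the lipid droplet and glucose metabolism lists changed in both directions. Of 19 lipid droplet genes 4 rose and 2 fell (8 and 4 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.144). Pparg, a regulator of fat storage, rose by 1.27 ± 0.22 and the lipid droplet gene Cidec by 2.80 ± 0.62, from 0.293 to 2.10 CPM, while Plin5 and Hsd17b13, which coat lipid droplets, fell by 0.66 and 0.61. Of 19 glucose metabolism genes 3 rose and 1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.857). Irs2, an insulin receptor substrate, rose from 8.65 ± 0.36 to 34.2 ± 10.9 CPM, a change of 1.98 ± 0.32 (edgeR adjusted p = 0.00916). Igfbp1 rose by 3.22 ± 0.58 and the gluconeogenic enzyme G6pc rose from 178.5 ± 24.3 to 470.3 ± 134.6 CPM. Angptl8, a feeding-induced hormone, changed by -3.38 ± 0.60. The adipocyte list had 3 members that rose of 6 (4 higher and 1 lower adjusted over the list alone), with a median of 1.10, a camera adjusted p of 0.00255, and adjusted p = 0.195 with an estimated correlation. Its largest change was in Cfd, adipsin, at 0.0633 CPM in the control and 9.34 ± 12.3 CPM in the model, and Car3, carbonic anhydrase 3, rose by 1.54 ± 0.24.

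Markers of endothelial cells, macrophages and lymphocytes were higher in the model. The endothelial list had 5 members that rose of 18 (13 adjusted over the list alone), with a median of 0.70 and a camera adjusted p of 3.6e-11, and adjusted p = 0.316 with an estimated correlation. Cdh5, Gpr182 and Stab2 rose by 1.00, 0.98 and 0.85. The macrophage list had 4 that rose of 28 (10 adjusted over the list alone), with a median of 0.69 and a camera adjusted p of 4.08e-09, and adjusted p = 0.337 with an estimated correlation. The Kupffer cell gene Clec4f rose by 0.83 ± 0.17, Mrc1 by 0.98 ± 0.18 and Cd68 by 0.98 ± 0.22. The interferon list had 2 that rose of 25 (4 higher and 1 lower adjusted over the list alone), with the RNA sensor Ddx58 higher by 0.52. Its median was 0.43, with a camera adjusted p of 7.16e-05, and adjusted p = 0.369 with an estimated correlation. T and natural killer cell genes (median 0.40, camera adjusted p = 0.0206) and B cell genes (1.34, camera adjusted p = 0.0103) also stood higher, with adjusted p = 0.693 and 0.465 with an estimated correlation. Control replicate 1 scored within the model range for T and natural killer cells (0.221), and control replicate 3 for hepatocytes (0.015). In the T cell list Cd4 rose by 1.65, and no B cell gene passed the gene test. The hepatocyte list stood lower with a median of -0.19 (camera adjusted p = 0.013, and adjusted p = 0.693 with an estimated correlation), and 1 of its 20 members fell, Hnf4a, a hepatocyte transcription factor, by 0.72 ± 0.15.

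The ribosomal protein list had 6 members that fell of 30 (23 adjusted over the list alone), with a median of -0.34 and a camera adjusted p of 3.6e-11, and adjusted p = 0.456 with an estimated correlation. Rps16 fell by 0.51 ± 0.11. The ribosomal protein, heat shock and immediate early lists were included for RNA quality and handling, which were not tested as a cause. Stress lists were lower too. The heat shock list had a median of -0.60 (camera adjusted p = 0.000715) and the endoplasmic reticulum stress list of -0.54 (0.000961), both with adjusted p = 0.481 with an estimated correlation. Control replicate 1 scored within the model range in both lists (0.004 and 0.022), so control replicates 2 and 3 carry the difference (1.38 and 1.28 for heat shock, 0.686 and 0.926 for endoplasmic reticulum stress). In each of them 1 member fell, the chaperone Dnajb1 by 1.18 and the stress transcription factor Ddit3 4.93-fold (95% interval of the log2 change -3.10 to -1.50). Immediate early genes had a median of -0.62 (camera adjusted p = 0.00247, and adjusted p = 0.393 with an estimated correlation), female-biased liver genes of -1.02 (0.0021, and adjusted p = 0.316 with an estimated correlation) and acute phase genes of -0.18 (0.0423, and adjusted p = 0.746 with an estimated correlation). Control replicate 3 scored within the model range for acute phase genes (-0.326). Cyp17a1 fell by 2.33 in the female-biased list and Socs3, a brake on cytokine signalling, fell by 1.22 in the acute phase list. The transcription factor Zbtb16 fell from 94.3 ± 24.4 to 14.8 ± 1.56 CPM, a change of -2.67 ± 0.29 (edgeR adjusted p = 0.00184). Other large changes were Mfsd2a, a lipid transporter, at -4.59 ± 0.94, the hydroxylase-related gene Moxd1 at 4.45 ± 0.67 and Adam11 at 2.75 ± 0.41.

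In all, 565 of 12658 genes passed between model and control, 278 higher and 287 lower. The authors' table has 1009 genes with a q value under 0.05, 506 higher and 503 lower. DESeq2 gave 967, which held 564 of the 565. The count was 919 without control replicate 1, 82 without control replicate 2, 123 without control replicate 3, 165 without model replicate 1, 319 without model replicate 2 and 83 without model replicate 5. Of the 47 passing genes that the naming rule took, 10 passed edgeR whichever library was left out (among them Srebf1, Tm7sf2, Abca1, Adam11, Car3, Ddit3, Irs2, Pparg and Zbtb16), and the highest adjusted p of each of the other 37 lay between 0.0515 and 0.196. Of 35 lists 15 passed camera, 7 higher and 8 lower. The threshold was missed by 4 of these without some library. Their camera adjusted p-values were as high as 0.387 for acute phase (without control replicate 1 or 2 or model replicate 2 or 5), 0.167 for T and natural killer cells (without control replicate 2 or 3 or model replicate 1), 0.149 for hepatocytes (without control replicate 1 or model replicate 2) and 0.0565 for immediate early genes (without model replicate 2).

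**Figure D1:**
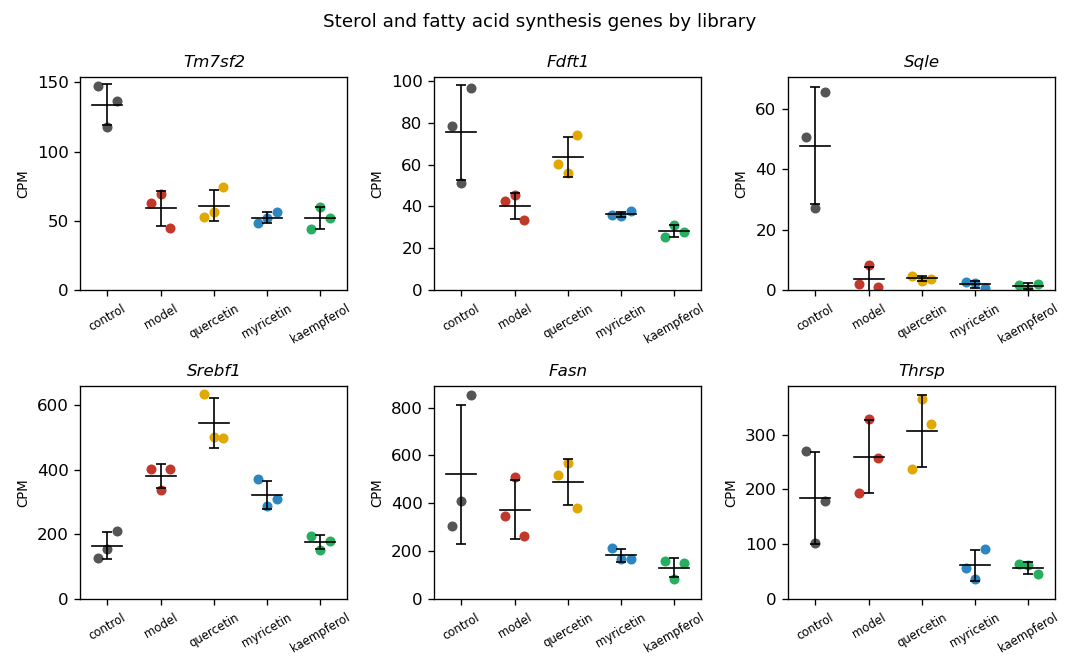
Levels of 6 sterol and fatty acid synthesis genes in CPM on the vertical axes, by group, with 1 point per library and bars for mean and SD (n = 3). Srebf1 stood at 164.8 CPM in the control, 379.7 in the model and 176.1 with kaempferol.

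Quercetin against the model asks how livers of the group given 200 mg/kg/day of this flavonol differed. Circadian clock genes had the highest share of passing members of any list. Of 19 clock genes tested 8 rose and 6 fell (10 and 6 adjusted over the list alone), and at least 13 of these 14 passed whichever library was left out. Dbp, a clock output transcription factor (chromosome 7, 45705100 to 45710203), rose from 2.67 ± 0.425 to 143.1 ± 18.7 CPM, a change of 5.74 ± 0.47 (edgeR adjusted p = 8.02e-05). Arntl, which encodes the core clock activator BMAL1 (chromosome 7, 113178471 to 113314126), fell from 28.6 ± 2.02 to 2.66 ± 1.17 CPM, a change of -3.43 ± 0.28 (edgeR adjusted p = 1.62e-05). The clock repressor Nr1d1 rose from 5.95 ± 1.56 to 116.8 ± 32.0 CPM, and Ciart and Bhlhe41 rose by 4.75 ± 0.62 and 2.92 ± 0.35. The repressor Cry1 changed by -2.83 ± 0.23 and the activator Npas2 stood at 7.49 ± 0.93 CPM in the model and 0.154 ± 0.0875 with quercetin. Members went both ways, and the directional list test did not pass (median 0.84, camera adjusted p = 0.142).

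Metabolic genes also differed with quercetin. Cyp8b1, the sterol hydroxylase that sets the share of cholic acid (chromosome 9, 121914356 to 121916305), fell from 501.5 ± 37.4 to 180.0 ± 68.0 CPM, a change of -1.48 ± 0.23 (edgeR adjusted p = 0.00178). It was 1 of 3 bile acid synthesis genes that fell of 16 (5 adjusted over the list alone), with Cyp7b1 at -1.59 ± 0.36 and Cyp2c70 at -0.93 ± 0.22. The list had a median of -0.16 and a camera adjusted p of 0.0133, and adjusted p = 0.77 with an estimated correlation. Of 14 sterol efflux genes 4 rose (5 adjusted over the list alone), with a median of 0.26 and a camera adjusted p of 0.0125, and adjusted p = 0.547 with an estimated correlation. The sterol transporter genes Abcg5 and Abcg8 rose by 1.36 ± 0.34 and 1.25 ± 0.30, Soat2, which esterifies cholesterol, by 0.65 ± 0.12, and Npc2 by 0.42 ± 0.11. Of 25 cholesterol synthesis genes 2 rose (2 adjusted over the list alone, median 0.03, camera adjusted p = 0.387). Other fixed genes did not pass edgeR, with Srebf1 at 0.52 ± 0.17 (adjusted p = 0.066), Fasn at 0.39 ± 0.37 (0.584), Sqle at 0.03 ± 0.74 (0.987), Scd1 at -0.27 ± 0.35 (0.697), Cpt1a at 0.28 ± 0.12 (0.163), Cyp7a1 at -0.01 ± 0.61 (0.996), Cd36 at -0.18 ± 0.44 (0.854) and Cyp1a1 at 0.78 ± 0.30 (0.123). The lipid droplet list (2 rose and 1 fell of 19, camera adjusted p = 0.584) and the glucose metabolism list (1 rose and 2 fell of 19, 0.175) did not pass as sets. Their passing genes include Plin2, which fell by 0.77, and the lipase gene Pnpla2, which rose by 0.55. The glycogen targeting gene Ppp1r3c fell by 1.98 ± 0.32, glycogen phosphorylase Pygl fell by 0.59 and glycogen synthase Gys2 rose by 0.56.

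The ribosomal protein list had 15 members that rose of 30 (26 adjusted over the list alone), with a median of 0.38 and a camera adjusted p of 1.84e-12, and adjusted p = 0.663 with an estimated correlation. Rps27 rose by 0.73 ± 0.13, Rps23 by 0.55 and Rps16 by 0.54. RNA quality and handling, for which the ribosomal protein list was included, were not tested as a cause. Male-biased liver genes had 5 members that fell of 17 (6 adjusted over the list alone), with a median of -0.48 and a camera adjusted p of 1.9e-07, and adjusted p = 0.611 with an estimated correlation. Elovl3, a fatty acid elongase, fell from 902.8 ± 106.4 to 100.2 ± 61.7 CPM (-3.17 ± 0.43, edgeR adjusted p = 0.00164), and Serpina1e and the complement gene C6 each fell by 0.84. Female-biased genes had 2 members that rose of 9 (6 adjusted over the list alone), with a median of 1.82 and a camera adjusted p of 0.00183, and adjusted p = 0.547 with an estimated correlation. They were the peroxisomal transporter Abcd2, at 2.35 ± 0.51, and the fatty acid hydroxylase Cyp4a14, at 4.95 ± 1.34. Both lists varied within the quercetin group. Mean male-biased scores relative to all libraries were -1.17 and -0.83 in quercetin replicates 2 and 5 and 0.02 in replicate 8, and female-biased scores were 1.22, 1.07 and 0.14.

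Of 26 acute phase genes 3 rose (3 adjusted over the list alone), the metallothioneins Mt1 at 4.54 ± 1.02 and Mt2 at 5.29 ± 1.21 and Socs3 at 2.08 ± 0.31, with a list median of 0.18 and a camera adjusted p of 0.0123, and adjusted p = 0.785 with an estimated correlation. The neutrophil list had a median of 1.22 (camera adjusted p = 0.0166, and adjusted p = 0.611 with an estimated correlation), with the calprotectin genes S100a8 and S100a9 higher by 2.20 and 1.66 at levels under 5 CPM. Interferon genes had a median of 0.23 (camera adjusted p = 0.0496, and adjusted p = 0.77 with an estimated correlation), with the antiviral genes Isg15 and Usp18 higher by 0.90 and 0.86, and Cmpk2 at -0.90. Endothelial (-0.31, camera adjusted p = 0.00905), heat shock (-0.45, 0.0163) and stellate cell lists (-0.30, 0.0375) had lower medians, with adjusted p = 0.77, 0.77 and 0.888 with an estimated correlation. In each of these lists 1 quercetin library scored within the model range, replicate 2 for endothelial (0.079) and replicate 5 for heat shock (0.145) and stellate cells (0.1). Vwf fell by 0.80 in the endothelial list and the chaperones Hsp90aa1 and Hsp90ab1 fell by 1.01 and 0.45 in the heat shock list. The stress kinase homolog Trib3 rose by 2.11 ± 0.30. Moxd1 stood at 36.5 ± 20.8 CPM in the model and 0.197 ± 0.186 with quercetin, and Nat8f5, an acetyltransferase homolog with near-identical relatives, changed by -2.70 ± 0.41.

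With quercetin 990 genes passed, 514 higher and 476 lower than in the model, and the authors' table has 957 with a q value under 0.05. The count was 434 without model replicate 1, 429 without model replicate 2, 602 without model replicate 5 and 546 without quercetin replicate 5. Of the 52 passing genes that the naming rule took, 24 passed whichever library was left out, among them the 7 clock genes named above, Cyp8b1, Elovl3, Soat2, Trib3, Isg15, Socs3, Moxd1 and Nat8f5, and the highest adjusted p of each of the other 28 lay between 0.0537 and 0.183. Of the 11 lists that passed camera, 5 missed the threshold without some library. Their camera adjusted p-values were as high as 0.12 for endothelial (without quercetin replicate 5), 0.11 for heat shock (without model replicate 2 or quercetin replicate 2 or 8), 0.339 for stellate cells (without model replicate 2 or quercetin replicate 8), 0.0888 for neutrophils (without model replicate 2 or quercetin replicate 5) and 0.102 for interferon (without model replicate 2 or 5 or quercetin replicate 2 or 5). With the clock score as a covariate, an alternative chosen after seeing the data, edgeR passed 0 genes (518 at an unadjusted p under 0.05), with a median SE of 0.513 in place of 0.162.

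**Figure D2:**
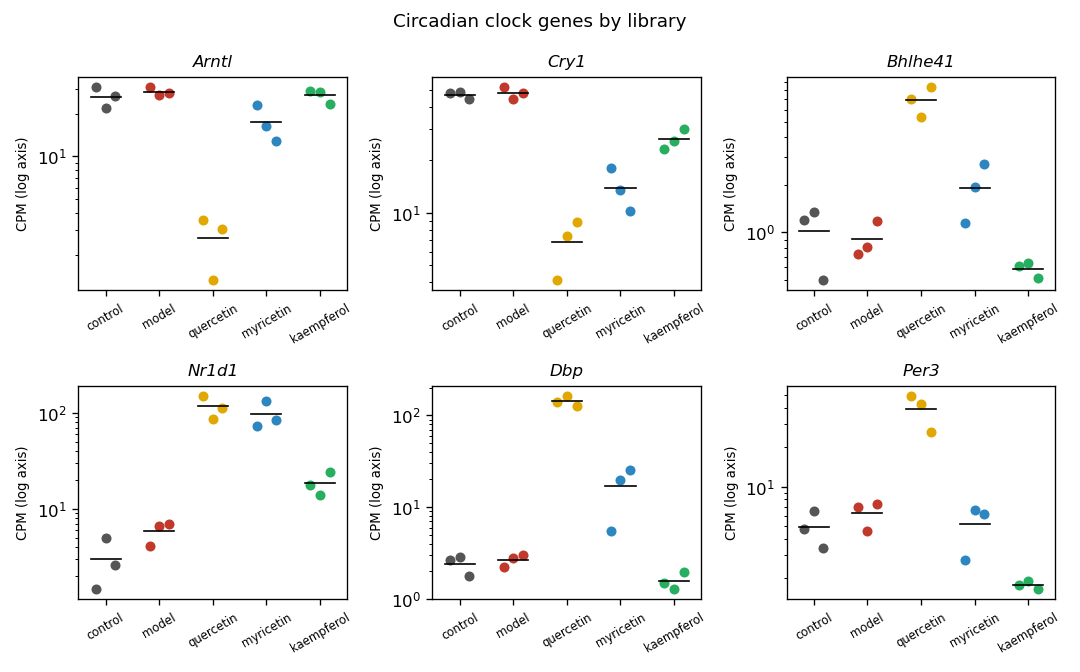
Levels of 6 circadian clock genes in CPM on logarithmic vertical axes, by group, with 1 point per library and a line at the mean (n = 3). Dbp stood at 2.67 CPM in the model, 143.1 with quercetin, 16.9 with myricetin and 1.58 with kaempferol.

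Myricetin against the model asks the same at 75 mg/kg/day. Clock genes changed here too, with 3 that rose and 2 that fell of 19 (4 and 6 adjusted over the list alone, median -0.09, camera adjusted p = 0.213). The libraries were uneven, with clock scores of -2.02 in myricetin replicate 5 and 2.00 and 3.37 in replicates 7 and 8, and from -3.55 to -3.34 in the model. Nr1d1 rose from 5.95 ± 1.56 to 97.2 ± 32.6 CPM (4.03 ± 0.40, edgeR adjusted p = 0.00173), Nr1d2 by 1.99 ± 0.29 and Dbp by 2.65 ± 0.45, and Cry1 changed by -1.80 ± 0.22. Outside the clock list, Trib3 rose by 2.18 ± 0.30 and the synaptic vesicle gene Syt1 by 1.58 ± 0.27, while the bile acid transporter Slc10a2 changed by -1.73 ± 0.34, the protease gene Capn8 by -1.62 ± 0.30, Nat8f5 by -2.56 ± 0.40 and Moxd1 by -3.44 ± 0.61.

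Cholesterol and fatty acid synthesis genes were lower with myricetin as sets, although no gene in these lists passed alone. Cholesterol synthesis genes had a median of -0.31 (camera adjusted p = 1.08e-07, and adjusted p = 0.617 with an estimated correlation). Fatty acid synthesis genes had a median of -0.30 (1.32e-05) and glucose metabolism genes of -0.39 (2.99e-05), both with adjusted p = 0.28 with an estimated correlation. Adjusted over the list alone, 4 fatty acid synthesis genes and 3 glucose metabolism genes were lower. Heat shock genes (-0.47, camera adjusted p = 0.00102, and adjusted p = 0.617 with an estimated correlation) and stellate cell genes (-0.29, 0.00171, and adjusted p = 0.759 with an estimated correlation) were lower as sets. Macrophage genes (0.31, 0.00259) and fatty acid oxidation genes (0.12, 0.0309, with 5 higher adjusted over the list alone) were higher as sets, both with adjusted p = 0.759 with an estimated correlation. Myricetin replicate 5 lay on the other side of every model library for stellate cells (0.485, against -0.492 and -0.731 in replicates 7 and 8) and for fatty acid oxidation (-0.41, against 0.413 and 0.373). Within the model range were the scores of replicate 5 for cholesterol synthesis (-0.368) and replicate 7 for macrophages (0.03). Single fixed genes did not pass edgeR, such as Fasn at -1.03 ± 0.38 (adjusted p = 0.297), Srebf1 at -0.23 ± 0.17 (0.631), Scd1 at -0.68 ± 0.35 (0.487), Cyp7a1 at -1.04 ± 0.62 (0.561), Cyp8b1 at -0.49 ± 0.23 (0.412) and Abcg5 at 0.88 ± 0.34 (0.318).

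With myricetin 50 genes passed edgeR, 23 higher and 27 lower, beside 206 by DESeq2 and 277 with a q value under 0.05 in the authors' table. The count was 18 without model replicate 1, 13 without model replicate 2, 14 without model replicate 5, 15 without myricetin replicate 7 and 15 without myricetin replicate 8, and 12 lists passed in place of 7 without model replicate 5. Of the 12 passing genes that the naming rule took, 4 passed whichever library was left out, among them Cry1, Nr1d1 and Trib3, and the highest adjusted p of each of the other 8 lay between 0.0502 and 0.215. Of the 7 lists, 4 missed the threshold without some library. Their camera adjusted p-values were as high as 0.542 for fatty acid oxidation (without model replicate 2 or myricetin replicate 7 or 8), 0.0783 for heat shock (without myricetin replicate 5), 0.0822 for macrophages (without model replicate 2 or myricetin replicate 8) and 0.179 for stellate cells (without myricetin replicate 7 or 8).

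Kaempferol against the model asks the same at 100 mg/kg/day, and 5 genes passed. Srebf1 fell from 379.7 ± 37.5 to 176.1 ± 22.1 CPM, a change of -1.11 ± 0.17 (edgeR adjusted p = 0.0224), near its control level of 164.8 ± 42.2 CPM. The acute phase gene Saa3 changed by 1.71 ± 0.26 (edgeR adjusted p = 0.0288). Nat8f6, named after its values were seen, also passed, with 3.27 ± 0.607 CPM in the model and 0.699 ± 0.187 with kaempferol, a change of -2.21 ± 0.33 (edgeR adjusted p = 0.0224), and it has near-identical relatives. Cholesterol synthesis genes were lower as a set, with a median of -0.61, 13 of 25 lower adjusted over the list alone and a camera adjusted p of 4.95e-17, and adjusted p = 0.114 with an estimated correlation. Fatty acid synthesis genes had a median of -0.42 with 1 that fell of 20, Srebf1 (6 adjusted over the list alone, camera adjusted p = 1.76e-09), and clock genes of -0.71 with 1 that fell of 19 (1 higher and 7 lower adjusted over the list alone, 6.88e-09), both with adjusted p = 0.0645 with an estimated correlation. Fasn stood at -1.52 ± 0.38 (edgeR adjusted p = 0.153), Cyp7a1 at -1.54 ± 0.63 (0.366), Cyp8b1 at -0.20 ± 0.22 (0.819), Abcg5 at 0.14 ± 0.33 (0.932) and Cpt1a at 0.40 ± 0.12 (0.179), and did not pass.

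Immune lists were higher with kaempferol as sets. Macrophage genes had a median of 0.79, with 17 of 28 higher adjusted over the list alone and a camera adjusted p of 1.82e-16, and interferon genes of 0.56, with 12 of 25 higher adjusted over the list alone and a camera adjusted p of 4.78e-10, both with adjusted p = 0.106 with an estimated correlation. Acute phase genes had a median of 0.47 with 1 that rose of 26, Saa3 (6 adjusted over the list alone, camera adjusted p = 3.97e-08, and adjusted p = 0.29 with an estimated correlation). B cell (1.07, camera adjusted p = 1.95e-05), neutrophil (0.90, 0.000956), chemokine (0.57, 0.000528), T and natural killer cell (0.49, 0.00528) and MHC class II genes (0.45, 0.00528) were higher as well, with adjusted p = 0.139, 0.133, 0.29, 0.484 and 0.464 with an estimated correlation. Immediate early (0.45, 0.00528), cell cycle (0.34, 0.0285), endothelial (0.22, 0.0235), NRF2 (0.19, 0.0285) and fatty acid oxidation genes (0.07, 0.0295) were higher with adjusted p = 0.306, 0.603, 0.603, 0.306 and 0.64 with an estimated correlation. Heat shock (-0.50, 0.000528), endoplasmic reticulum stress (-0.42, 0.000721) and glucose metabolism genes (-0.21, 3.1e-05) were lower with adjusted p = 0.362, 0.362 and 0.106 with an estimated correlation. In 7 of these lists some kaempferol libraries scored within the model range. They were replicate 8 for acute phase (-0.32) and endoplasmic reticulum stress (-0.058), and replicate 5 for chemokines (-0.203), MHC class II (-0.119) and T and natural killer cells (0.322). Replicates 3 and 5 did so for immediate early (-0.113 and -0.03) and endothelial genes (0.218 in each).

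DESeq2 gave 197 genes for kaempferol and the authors' table has 278 with a q value under 0.05. The edgeR count was 1 without model replicate 1, 39 without kaempferol replicate 5 and 18 without kaempferol replicate 8, and it was 0 without model replicate 2, model replicate 5 or kaempferol replicate 3 (1096, 1276 and 1208 genes at an unadjusted p under 0.05). None of the 4 genes taken by the rule passed in every such fit, with edgeR adjusted p-values as high as 0.112 for Srebf1 without model replicate 1 and 0.208 for Saa3 without model replicate 2. Of the 19 lists that passed camera, 12 passed whichever library was left out. For the others the highest camera adjusted p was 0.548 for fatty acid oxidation (lost without model replicate 2 or 5 or kaempferol replicate 3 or 5), 0.237 for NRF2 (model replicate 5 or kaempferol replicate 3 or 5), and 0.327 for MHC class II (model replicate 2 or kaempferol replicate 3). It was 0.103 for T and natural killer cells (model replicate 2), 0.388 for endothelial (model replicate 1 or kaempferol replicate 8), 0.201 for cell cycle (kaempferol replicate 5) and 0.175 for immediate early genes (model replicate 2 or kaempferol replicate 8).

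**Figure D3:**
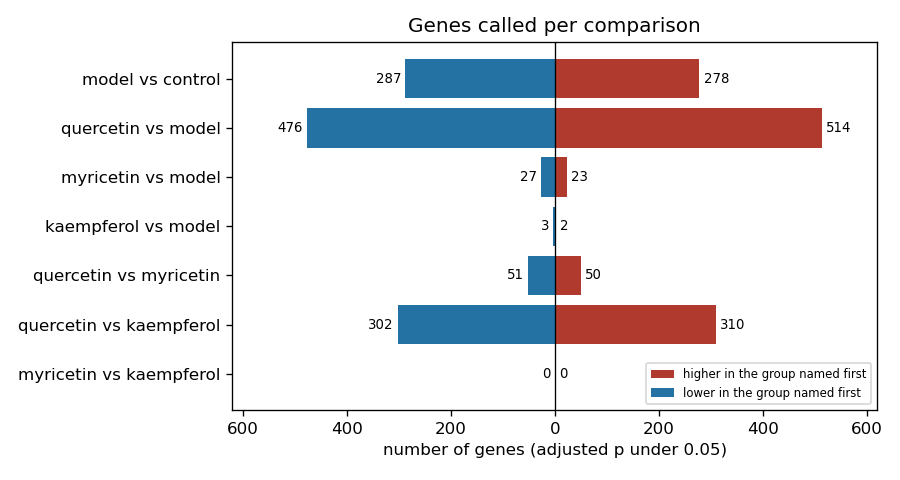
Number of genes with an adjusted p under 0.05 in each comparison on the horizontal axis, higher to the right and lower to the left. Quercetin against the model had 514 higher and 476 lower, and kaempferol against the model had 2 higher and 3 lower.

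**Figure D4:**
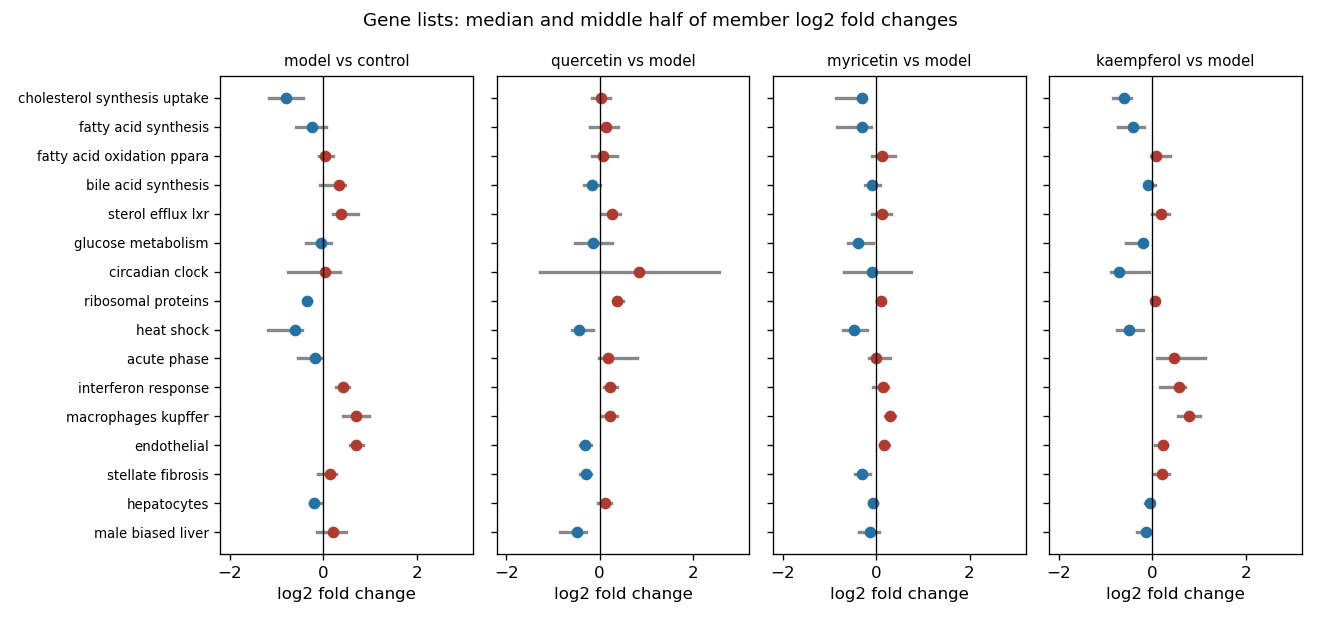
Medians of the log2 fold changes of 16 gene lists as points, with bars for the middle 50% of the members, for 4 comparisons. The cholesterol list had medians of -0.81 in the model against the control and 0.03, -0.31 and -0.61 with quercetin, myricetin and kaempferol against the model.

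Genes altered by the diet were compared with those altered by each flavonoid. Of the 565 genes that differed between model and control, 131 moved the opposite way with quercetin, 59 of them raised by the diet and 72 lowered, and 10 moved the same way. Independent lists of these sizes give 22.1 of either kind. The ribosomal gene Rps16 was among the genes lowered by the diet and raised with quercetin, and Moxd1 was raised by the diet and lowered with quercetin. Across all genes, which are not independent replicates, the covariance of the changes was -0.0956 against a simulated -0.0366 (r = -0.413 against -0.252), a difference of -0.059. With myricetin 10 genes moved the opposite way (1.11 in independent lists), with a covariance of -0.0483 against -0.0369 (r = -0.272 against -0.254), a difference of -0.0114. With kaempferol 2 genes did, Srebf1 and Nat8f6 (0.11 in independent lists), with a covariance of -0.015 against -0.0367 (r = -0.082 against -0.252), a difference of 0.0217. The model libraries stand on both sides and cannot be split into parts of at least 2, so part of any excess may come from them. The quercetin count was 22 without control replicate 2, 35 without control replicate 3, 39 without model replicate 1, 45 without model replicate 2, 14 without model replicate 5 and 80 without quercetin replicate 5. The myricetin count was 2 without control replicate 2, control replicate 3, model replicate 1 or myricetin replicate 7, 1 without model replicate 2 or 5, 3 without myricetin replicate 8 and 18 without myricetin replicate 5. That of kaempferol was 1 without control replicate 2, control replicate 3 or model replicate 1, 5 without kaempferol replicate 8 and 0 in edgeR without model replicate 2, model replicate 5 or kaempferol replicate 3, beside 28 by DESeq2 with all libraries.

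Quercetin and myricetin moved 44 genes the same way against the model, 21 higher and 23 lower, where independent lists give 1.95. The clock genes Cry1, Nr1d1 and Dbp, Trib3, Nat8f5 and Moxd1 were among them. The covariance was 0.1178 against a simulated 0.0369 (r = 0.645 against 0.505), a difference of 0.0809. Kaempferol shared 3 genes with quercetin (0.19 in independent lists; covariance 0.0795 against 0.0369, r = 0.421 against 0.505, difference 0.0426) and the same 3 with myricetin (0.01 in independent lists; covariance 0.0858 against 0.037, r = 0.593 against 0.504, difference 0.0488). Among the 3 was Nat8f6, lower with each flavonoid. All 3 flavonoid groups share the 3 model libraries, and part of the excess may come from them. The count for quercetin and myricetin was 18 without model replicate 1, 13 without model replicate 2 or 5 and 15 without myricetin replicate 7 or 8. The other pairs each had 0 in edgeR without model replicate 1, 2 or 5 or kaempferol replicate 3 (65 and 52 by DESeq2 with all libraries), and 10 and 7 without kaempferol replicate 5, and quercetin and kaempferol had 7 without kaempferol replicate 8.

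The 3 compounds are flavonols that differ in the hydroxyl groups of the B ring, 1 in kaempferol, 2 in quercetin and 3 in myricetin. Their doses differed, at 100, 200 and 75 mg/kg/day, and the time of collection is not known. Structure, dose and time of day are thus not separated in what follows. Among the 4 high-fat groups 616 genes differed in the edgeR F test. That count was 347 without model replicate 1, 355 without model replicate 2, 409 without model replicate 5 and 375 without quercetin replicate 5, and DESeq2 gave 1335.

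Quercetin against myricetin had higher cholesterol and fatty acid synthesis genes. Of 25 cholesterol genes 2 were higher (9 adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 3.81e-12, and adjusted p = 0.36 with an estimated correlation. Of 20 fatty acid synthesis genes 2 were higher (11 adjusted over the list alone), with a median of 0.50 and a camera adjusted p of 5.16e-10, and adjusted p = 0.0981 with an estimated correlation. They were Thrsp, a lipogenic regulator, at 2.31 ± 0.40 and Srebf1 at 0.75 (95% interval 0.40 to 1.10, edgeR adjusted p = 0.0445). Fasn differed by 1.42 (0.59 to 2.25, edgeR adjusted p = 0.134) and did not pass. Of 19 clock genes 5 were higher and 2 lower with quercetin (9 and 5 adjusted over the list alone, median 0.53, camera adjusted p = 0.00019, and adjusted p = 0.36 with an estimated correlation), with Dbp at 3.09 ± 0.39, Per3 at 2.92 ± 0.32, Ciart at 3.87 ± 0.57, Arntl at -2.72 ± 0.28 and Clock at -0.98 ± 0.15. The cell cycle inhibitor Cdkn1a was lower by a log2 change of -2.31 ± 0.33 and Lrfn3 by -1.92 ± 0.19. In total 101 genes passed edgeR, 50 higher and 51 lower, against 269 by DESeq2. The count was 35 without quercetin replicate 2, 33 without quercetin replicate 5, 202 without quercetin replicate 8, 26 without myricetin replicate 5 and 30 without myricetin replicate 7. Of the 18 passing genes of the rule, 7 passed whichever library was left out, among them Arntl, Clock, Dbp, Per3, Cdkn1a and Lrfn3, and the highest adjusted p of each of the other 11 lay between 0.0579 and 0.203. In all, 18 lists passed camera, 15 higher and 3 lower, and none passed with an estimated correlation. Ribosomal proteins had the smallest camera adjusted p (1.22e-13), and the endothelial list passed too (6.69e-09). Of the 18 lists, 12 missed the threshold without some library.

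Cholesterol synthesis, fatty acid synthesis and clock genes also differed between quercetin and kaempferol. Of 25 cholesterol genes 10 were higher with quercetin (12 adjusted over the list alone), with a median of 0.66 and a camera adjusted p of 6.7e-13, and adjusted p = 0.408 with an estimated correlation. Fdft1 differed by 1.18 ± 0.19. Of 20 fatty acid synthesis genes 5 were higher (12 adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 1.45e-08, and adjusted p = 0.0806 with an estimated correlation. Srebf1 differed by 1.63 (1.27 to 1.99, edgeR adjusted p = 5.57e-05), Thrsp by 2.42 ± 0.40 and Fasn by 1.90 (1.06 to 2.75, 0.0175). Fasn did not pass in 3 of the 6 fits without 1 library (edgeR adjusted p up to 0.0596, without quercetin replicate 5). Cyp8b1 was lower with quercetin by a log2 change of -1.28 ± 0.23 (edgeR adjusted p = 0.00556). Of 19 clock genes 12 were higher and 5 lower (13 and 6 adjusted over the list alone, median 1.90, camera adjusted p = 1.45e-08, and adjusted p = 0.0624 with an estimated correlation), with Dbp at 6.48 ± 0.49, Per3 at 4.47 ± 0.36 and Arntl at -3.35 ± 0.28. Endothelial genes were lower, 4 of 18 (8 adjusted over the list alone, median -0.52, camera adjusted p = 7.14e-07, and adjusted p = 0.581 with an estimated correlation), with Pecam1 at -1.01 ± 0.21. In total 612 genes passed edgeR, 310 higher and 302 lower, against 958 by DESeq2. The count was 359 without quercetin replicate 2, 335 without quercetin replicate 5, 285 without kaempferol replicate 3 and 391 without kaempferol replicate 8. Of the 35 passing genes of the rule, 20 passed in each of these fits, and the highest adjusted p of each of the other 15 lay between 0.0596 and 0.169.

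Myricetin against kaempferol gave 0 genes by edgeR, with 925 at an unadjusted p under 0.05 and 34 by DESeq2. Among the smallest edgeR p-values, none of which passed, were those of Saa3 (-1.76 ± 0.26), the cold-inducible RNA-binding gene Rbm3 (0.66 ± 0.11), Carmil1 (1.17 ± 0.20) and Dbp (3.40 ± 0.49), each with an adjusted p of 0.0713, and of Lgalsl (-0.65 ± 0.13, 0.163). Srebf1 stood at 323.1 ± 43.1 CPM with myricetin and 176.1 ± 22.1 with kaempferol, a difference of 0.88 with a 95% interval of 0.52 to 1.23 (edgeR adjusted p = 0.145). As sets, macrophage genes were lower with myricetin (median -0.50, camera adjusted p = 9.6e-08, and adjusted p = 0.319 with an estimated correlation), as were T and natural killer cell genes (-0.83, 1.22e-07, and adjusted p = 0.288 with an estimated correlation). Kaempferol replicate 5 scored within the myricetin range for macrophages (0.223). Clock genes were higher (1.01, 4.77e-07, and adjusted p = 0.159 with an estimated correlation), with 9 higher and 5 lower of 19 adjusted over the list alone. In all, 13 lists passed camera, 3 higher and 10 lower with myricetin, and none passed with an estimated correlation. Acute phase (camera adjusted p = 9.6e-08), stellate cell (1.22e-07), interferon (1.32e-06) and cell cycle genes (8.77e-06) were among them. Of the 13 lists, 4 missed the threshold without some library. The count of genes was 2 without myricetin replicate 5 and 13 without kaempferol replicate 8.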

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

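Tests chosen only after the result was seen are the time of collection, both tests on insulin-regulated genes, and the hepatocyte share and blood tests and the T cell and MHC class II test for kaempferol. The clock score as a covariate was also added afterwards. For the reach of the clock difference to other genes, the comparison with other splits was not part of the prediction written beforehand.

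The effects of quercetin against the model differed from those of the other flavonoids by a direct test, while myricetin and kaempferol differed in 0 genes by edgeR (925 at an unadjusted p under 0.05, and 34 by DESeq2). Quercetin and myricetin differed in 101 genes, with Srebf1 higher with quercetin by 0.75 on the log2 scale. Quercetin and kaempferol differed in 612 genes, with Srebf1 higher with quercetin by 1.63 and Fasn by 1.90. The Fasn result did not pass in 3 of the 6 fits without 1 library (edgeR adjusted p up to 0.0596, without quercetin replicate 5). Srebf1 between quercetin and myricetin did not pass in 5 of 6 such fits (up to 0.18, without myricetin replicate 7). With the clock score as a covariate, 0 genes passed edgeR in either comparison. The median SE then rose from 0.161 to 0.348 for quercetin against myricetin and to 0.559 for quercetin against kaempferol. The doses differed and the labels give no time of collection, so compound, dose and time of day are not separated.

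The first pattern weighed is the shift of clock genes with quercetin. Dbp lay between 125.5 and 162.8 CPM in the quercetin libraries and between 2.21 and 3.03 in the model, and at least 13 of the 14 clock genes that passed still passed without any single library, which argues against a single library as the source. A different time of day at collection may account for the pattern, as 93.4% of the variance of the clock score lay between groups and the labels give no time, so time of day and treatment cannot be told apart. Whether the difference reaches genes outside the clock list also stays open. The comparisons of quercetin against the model and of myricetin against kaempferol share no library. Over the 12639 other genes their changes had an r of 0.202, which met the value set beforehand for such a reach. The highest r in simulations of unchanged groups was 0.069, but these drew genes independently, so their spread is a lower limit. Against other splits, a comparison not in that prediction, 22.7% of 1000 gave an r as far from 0. A biological effect of quercetin on the clock stays open as well.

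The second pattern is that of 4 insulin-regulated genes in the model, picked after the results were seen with no fixed list behind them, with Angptl8 lower and Irs2, Igfbp1 and G6pc higher than in the control. Of these, only Irs2 passed whichever library was left out. Without some library, edgeR adjusted p-values reached 0.0654 for Angptl8, 0.073 for Igfbp1 and 0.086 for G6pc. The glucose metabolism list did not pass (camera adjusted p = 0.857), and Srebf1, which insulin induces, rose by 1.20. A lower share of hepatocytes would lower all 4 alike, but Irs2, Igfbp1 and G6pc rose. The hepatocyte list had a median of only -0.193. The 4 genes were picked with their directions known, so this is no independent test. It shows only that a lower share would not by itself give those rises. A longer time since feeding in the model libraries may account for the pattern. The fatty acid oxidation list, which fasting raises, had a median of 0.036 and a mean of -0.248. Adjusted over the list alone, 2 of its members were higher and 4 lower. Members thus went in both directions, and a longer time since feeding and a diet effect cannot be told apart.

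The third pattern is the higher immune lists with kaempferol. A lower share of hepatocytes would raise other cell types alike, yet the stellate list had a median of 0.202 and the cholangiocyte list of -0.179 where the macrophage list had 0.789. Stellate scores were split by library (0.743, -0.623 and 0.564 in kaempferol replicates 3, 5 and 8), but without kaempferol replicate 5 the stellate and macrophage medians were 0.427 and 0.968, with the middle 50% of members still apart. No single library accounts for the macrophage list, with a lowest median of 0.52 (without kaempferol replicate 8), but a single library stays open for the T cell and MHC class II lists, with camera adjusted p-values up to 0.103 without model replicate 2 and 0.327 without model replicate 2 or kaempferol replicate 3. Blood left in the tissue could contribute and cannot be told apart from an effect of kaempferol, with an erythroid list median of 0.597 (6 genes, camera adjusted p = 0.194). Erythroid scores were -0.376, 0.69 and 0.722 in kaempferol replicates 3, 5 and 8 and ran from -0.468 to 0.555 in the model. The erythroid rise thus rests on replicates 5 and 8. Kaempferol replicate 3 lay within the model range, yet its macrophage score of 0.544 was above that of every model library (at most 0.149).

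Other splits of the libraries were refitted for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, the real split gave 565 in the model against the control, 990 with quercetin and 50 with myricetin, each with a highest other split of 0 by edgeR, and 5 with kaempferol, with a highest other of 1. It gave 101 for quercetin against myricetin and 612 for quercetin against kaempferol, each with a highest other of 2. In each of these, 1 of the 10 splits, the real one, was as large. For myricetin against kaempferol the real count was 0 and the highest other 26, so that all 10 splits were as large. For lists, the real and the highest other counts were 15 and 14 in the model against the control (1 of 10 as large), 11 and 13 with quercetin (5 of 10), 7 and 18 with myricetin (8 of 10), 19 and 20 with kaempferol (2 of 10), 18 and 12 for quercetin against myricetin (1 of 10), 11 and 15 for quercetin against kaempferol (5 of 10) and 13 and 14 for myricetin against kaempferol (4 of 10). Numbers of lists near the real ones also came from other splits. For the 616 genes that differed among the 4 high-fat groups, 1 of 100 splits, the real one, was as large and the highest other had 19 genes. A chance division of the libraries is thus an unlikely source of this count. The splits cannot part the treatment from anything else that differed by group, such as the time of collection.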

How the results depend on the processing

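The clock score as a covariate was chosen after seeing the data, and every other alternative before. RLE factors and a filter at a mean of 1 CPM (11625 genes) kept every count of genes and of opposed or shared genes within 1.5 times. Gene lists were not tested again under these settings. Depth was even across libraries, and the 3 libraries per group limit the precision, with a median 95% interval of 0.344 to either side of a log2 fold change. The alternatives for files with FPKM alone were not run, since the file holds counts. The cause of a change was not tested unless stated. No gene tested for the text that passed changed direction under any alternative run on it.

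Asking for at least a 2-fold change gave, by construction, fewer genes, 170 for the model against the control, 247 with quercetin, 24 with myricetin, 40 for quercetin against myricetin and 182 for quercetin against kaempferol, and 33 and 3 opposed genes with quercetin and myricetin and 20 shared between these. At an adjusted p under 0.1, the opposed genes were 307, 28 and 7 with quercetin, myricetin and kaempferol, and the shared genes 99 for quercetin and myricetin, 24 for quercetin and kaempferol and 18 for myricetin and kaempferol. Without a filter on low counts (16775 genes) kaempferol had 18 genes and shared 7 with quercetin and 5 with myricetin. With only the 2 groups compared, which leaves fewer libraries, myricetin had 125 genes, kaempferol 21, quercetin against myricetin 10, quercetin against kaempferol 251 and myricetin against kaempferol 2.

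DESeq2 gave 967 genes for the model against the control, 206 with myricetin, 197 with kaempferol, 269 for quercetin against myricetin, 958 for quercetin against kaempferol, 34 for myricetin against kaempferol and 1335 among the high-fat groups. Opposed genes were then 250, 46 and 28 with quercetin, myricetin and kaempferol, and shared genes 149, 65 and 52. With the clock score as a covariate edgeR gave 282 genes for the model against the control, 8 with myricetin, 15 with kaempferol, 1 for myricetin against kaempferol and 14 among the high-fat groups. It gave 0 with quercetin, 0 for quercetin against myricetin and 0 for quercetin against kaempferol. At an unadjusted p under 0.05 these had 518, 567 and 573 genes, no more than chance alone gives at that threshold. DESeq2 without the covariate gave 1268, 269 and 958 at an adjusted p under 0.05. For quercetin the median SE rose from 0.162 to 0.513 and the median size of change of the genes that had passed went from 0.62 to 0.37, so the score and the group overlap.

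Camera with an estimated correlation passed 0 of 35 lists in each of the 7 comparisons, with smallest adjusted p-values between 0.0624 and 0.547. Fry passed 8 lists in the model against the control, 4 with quercetin, 0 with myricetin (8 by fry in either direction, 7 by camera), 5 with kaempferol, 1 for quercetin against myricetin, 3 for quercetin against kaempferol and 0 for myricetin against kaempferol (5 by fry in either direction, 13 by camera).

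The numbers in the library titles gave no sign of pairing the samples. Of 14 pairs of libraries with the same number in different groups, 0 had a correlation over 0.1 (mean -0.046, from -0.225 to 0.095), and the other 76 pairs had a mean of 0.009. The replicate block, which leaves 5 residual degrees of freedom, gave 43 genes for the model against the control, 236 with quercetin, 5 with myricetin, 1 with kaempferol, 6 for quercetin against myricetin, 185 for quercetin against kaempferol, 1 for myricetin against kaempferol and 131 among the high-fat groups. Opposed genes under the block were 7, 3 and 1, shared genes 5, 1 and 1, and lists 17 with quercetin and 13 with myricetin. Under the block Cyp8b1 in the model was at -0.117, Cyp7a1 and Scd1 with quercetin at 0.339 and 0.047 and Cd36 with myricetin at 0.136, each with the sign turned, and none of them passed before.

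Leaving out 1 library at a time gave 82 to 919 genes for the model against the control, 429 to 788 with quercetin, 13 to 65 with myricetin, 0 to 39 with kaempferol, 26 to 202 for quercetin against myricetin, 285 to 706 for quercetin against kaempferol, 0 to 13 for myricetin against kaempferol and 347 to 702 among the high-fat groups. Opposed genes were 14 to 173 with quercetin, 1 to 18 with myricetin and 0 to 5 with kaempferol, and shared genes 13 to 58 for quercetin and myricetin, 0 to 10 for quercetin and kaempferol and 0 to 7 for myricetin and kaempferol. Lists were 6 to 12 with myricetin (12 without model replicate 5) and 11 to 17 for quercetin against myricetin (11 without myricetin replicate 7). Some fixed genes that did not pass turned sign. Cpt1a in the model ran from -0.108 to 0.035 (above 0 without control replicate 1), Cyp8b1 from -0.08 to 0.214 (-0.032, -0.08 and -0.017 without control replicate 2, control replicate 3 and model replicate 1) and Fasn from -0.78 to 0.069 (above 0 without control replicate 3). With quercetin Cyp7a1 ran from -0.233 to 0.301 (0.004, 0.026 and 0.301 without model replicate 1, model replicate 2 and quercetin replicate 8), Sqle from -0.418 to 1.398 (-0.273, -0.418 and -0.158 without model replicate 1, model replicate 5 and quercetin replicate 2) and Cd36 from -0.662 to 0.332 (0.332 and 0.039 without model replicate 5 and quercetin replicate 8). With myricetin Sqle ran from -1.407 to 0.397 (above 0 without model replicate 2) and Cd36 from -0.293 to 0.49 (0.49, 0.051 and 0.057 without model replicate 5, myricetin replicate 5 and myricetin replicate 7), and with kaempferol Abcg5 ran from -0.168 to 0.415 (below 0 without model replicate 2). The oxidative phosphorylation list of quercetin against myricetin, at a camera adjusted p of 0.0393, ran from 0.000676 to 0.78 and turned direction at 0.78 without quercetin replicate 8. Of the values of named genes under all alternatives, 1958 kept their side of the threshold and direction, 565 no longer passed, 22 passed newly and 22 turned sign.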

Other observations

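The values in this part were picked after the results were seen, and no test was added for them.

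Other lists of these comparisons are given here, none of which passed camera. Between model and control, lipoprotein genes (1 higher and 1 lower of 23, 2 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.298), bile acid synthesis genes (1 and 1 of 16, 7 and 1 adjusted over the list alone, 0.33, 0.0555), chemokine genes (median 0.32, 0.0897) and male-biased liver genes (1 higher of 17, 0.22, 0.123) did not pass as lists, and neither did oxidative phosphorylation (-0.08, 0.478), bile acid transport (0.16, 0.402), xenobiotic (-0.01, 0.857), aryl hydrocarbon receptor (0.08, 0.857), cholangiocyte (-0.45, 0.38), stellate cell (0.15, 0.417) and erythroid genes (-0.17, 0.829). With quercetin, NRF2 genes had 3 that rose and 1 that fell of 28 (4 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.15), with the glutathione genes Gpx4, Gstm1 and Gstm3 higher by 0.46, 0.60 and 0.97 and Gclc at -0.67, and endoplasmic reticulum stress genes had 1 that rose and 3 that fell of 20 (median -0.44, 0.109), with Pdia4 at -0.82. Without some libraries none of these 5 genes passed edgeR, with adjusted p-values as high as 0.0866 for Gpx4 (model replicate 2), 0.183 for Gstm1 (model replicate 5), 0.119 for Gstm3 (model replicate 5), 0.0887 for Gclc (model replicate 1) and 0.0807 for Pdia4 (model replicate 2).

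The level of Moxd1, a monooxygenase homolog, followed the groups unevenly, at 1.66 ± 0.439 CPM in the control, 36.5 ± 20.8 in the model, 0.197 ± 0.186 with quercetin, 3.38 ± 2.92 with myricetin and 5.00 ± 2.10 with kaempferol (SD, n = 3). Nat8f6 had 1.43 ± 0.167 CPM in the control, 3.27 ± 0.607 in the model, 0.569 ± 0.228 with quercetin, 0.703 ± 0.265 with myricetin and 0.699 ± 0.187 with kaempferol. Mean heat shock scores on the log2 scale were 1.38 and 1.28 in control replicates 2 and 3 and 0.004 in control replicate 1, and ran from -0.06 to 0.33 in the model. The metallothioneins Mt1 and Mt2 varied within the quercetin group, at 31.7 ± 21.4 and 11.5 ± 7.42 CPM.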
